A study of Mus musculus with 12 samples.

How the data were processed

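Liver messenger RNA was measured by polyA-selected RNA sequencing in 12 liver samples of male mice fed a high-fat diet (60 kcal% fat, begun at 7 to 8 weeks of age) for 3 months. There were 6 libraries from mice lacking prohibitin 1 in adipocytes (KO) and 6 from wild-type mice (WT). Groups and replicate numbers were taken from the sample titles. No label says which library came from which animal or preparation day, so p-values measure the spread between these 12 libraries.

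The deposited table held whole-number read counts per gene and library, which were not normalized by the authors, per the file headers and the values. The same table held the authors' own comparison of KO with WT: a log2 fold change, a test score, a p-value and an adjusted p-value per gene, in columns named as DESeq2 writes them, per the file headers. FastQC, Trimmomatic, HISAT2, SAMtools, featureCounts and DESeq2 and the mouse genome build GRCm38 are named per the submitters' processing notes, which give no versions. The annotation release, the strand setting and the treatment of reads shared between genes are not given in the sources used here. Reads from overlapping or antisense genes, and from near-identical copies, therefore cannot be told apart. Called genes named here are marked as uncertain where they overlap another tested gene moving in the same direction, or have close copies. The marking may not be complete. Among the other named genes, Rtp4, Agpat2, Acaa1a, Srebf1 and Timp1 also overlap a tested gene. The deposited mean count per gene was not the mean over these 12 libraries: the ratio of the recomputed mean to it had a median of 1.121 (range 0.0482 to 2.62), while the authors' deposited log2 fold change had r = 0.9999 across genes with the log2 ratio of the group means.

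The table had 15344 rows for 15140 genes. The 204 repeated rows of a gene, whose counts were the same as in its first row, were left out. Symbols and positions came from GENCODE M21 (GRCm38) for 15127 genes. The lowest sum of counts of a gene over the 12 libraries was 15. Total counts ran from 30348123 to 40828767 per library. All 30 pairs of libraries within a group differed by more than sampling noise (chi-square per degree of freedom 38.49 to 245.29), so none looked like a library deposited in duplicate. This does not show that they came from separate animals, and n = 6 rests on the labels.

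Differences were tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood F test with robust estimation, on the deposited counts with TMM scaling and filterByExpr, which kept 15000 genes and removed 140. Tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. The test gives no standard error (SE) of the log2 fold change. Each SE was derived as the absolute log2 fold change, fitted without shrinkage, divided by the square root of the F value. On simulated counts drawn from the real means and library sizes (14959 genes tested, KO against WT, 200 planted changes), 52.2% of 1.5-fold, 83.6% of 2-fold and 97% of 4-fold changes were recovered, and 5.17% of the calls were unchanged genes. The planted genes had a mean of at least 1 CPM, and 21 genes of 1 list were also raised 1.5-fold. Genes were drawn independently of each other, so these shares may not hold for the real libraries. At this depth and number of replicates, many 1.5-fold changes were missed in the simulation, and smaller ones were not planted.

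A total of 45 gene lists were fixed before the data were examined, and the 44 with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation 0.01). A list score per library, the mean of standardised log2 CPM over the list's members, was tested by an exact two-sided permutation over all splits of 6 against 6, whose smallest p is 0.00216. The list of acinar pancreas genes had 1 measured member of 15 and was not tested. The text names Phb and Phb2, the 10 largest rises and 10 largest falls by log2 fold change among called genes with a mean of at least 1 CPM, up to 4 members with the smallest p of each list described, and fixed genes for steatosis, inflammation and fibrosis, of which 1 is not reported here. Predicted genes were only counted. This rule was also set before the data were examined. As an exception to it, the 7 genes beside Adipoq, predicted genes among them, 5 genes of lists that were not called, and the division of clock genes by phase were chosen after their values were seen.

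Alternatives set beforehand were DESeq2 1.42.0, limma-voom with and without library weights, RLE size factors, total counts only, no filter or at least 1 CPM in 6 libraries, a replicate block, 1 surrogate variable (sva 3.50.0), a 1.5-fold minimum, an estimated correlation, fry and the list permutation for the lists, and each library left out. Those chosen after seeing the data were a clock phase score and a macrophage score as covariates. For values of single genes and lists, these scores were not used on the genes they are made of. The counts over all genes include those genes. The alternatives were followed for 105 genes, of which 45 were called. A fit leaving out 2 KO libraries, picked by their low level of 1 gene, was also run. It is not reported, because choosing libraries by an outcome biases the comparison. A rank of the Adipoq region among regions of this same comparison was replaced by a test over regroupings of the libraries, because the region had been picked for its values, and that test has the same weakness. A test of the clock phase score with each library left out was replaced by one of the clock list fixed beforehand, because the genes of the score had been picked for their values.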

Results

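Liver RNA was sequenced in 12 samples from male mice on a high-fat diet for 3 months, 6 with prohibitin 1 deleted in adipocytes (KO) and 6 wild-type (WT). The study set out to learn how loss of this mitochondrial scaffold protein in fat cells alters fat accumulation, inflammation and fibrosis in the liver. Total counts per library ran from 34121087 to 37973022 in KO and from 30348123 to 40828767 in WT (exact permutation test of the difference, p = 0.742). The 10 most abundant genes took 17.8% ± 1.37 and 17.9% ± 2.26 of counts (SD, n = 6 each).

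Phb, which encodes prohibitin 1 (ENSMUSG00000038845, chromosome 11, 95666957 to 95680773, GRCm38), was present at similar levels in both groups. It stood at 90.8, 92.3, 96.5, 100, 88.6 and 97.0 CPM in KO libraries 1 to 6, and at 85.3, 91.2, 85.9, 86.1, 82.6 and 80.0 CPM in WT libraries 1 to 6. The log2 fold change was 0.15 ± 0.05 (SE, n = 6 per group; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.144), and 4 of 6 KO libraries lay above all WT libraries. An exact permutation test of log2 CPM for this gene alone gave p = 0.00649, unadjusted. Its partner Phb2 had a log2 fold change of -0.11 ± 0.07 (SE; edgeR, Benjamini-Hochberg adjusted p = 0.372). The deletion was directed to adipocytes, so liver RNA does not check the genotype labels.

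The comparison of KO with WT asks which liver genes differed between the genotypes. Serpina3c, a serine protease inhibitor gene, rose most, from 0.444 ± 0.389 to 19.4 ± 14.7 CPM (SD, n = 6 each; log2 fold change 5.48 ± 1.07 SE), although KO libraries 2 and 4 held 0.505 and 0.786 CPM and the other 4 held 24.4 to 31.2. Elovl3, a fatty acid elongase gene, rose 4.51-fold (log2 2.17 ± 0.36 SE) and was higher in 6 of 6 KO libraries than in any WT library. Acot3 and Acot4, which encode peroxisomal acyl-CoA thioesterases, fell by 4.00 ± 0.79 and 1.89 ± 0.34 on the log2 scale (SE). Acot3 ran from 2.10 CPM in WT library 6 to 98.2 CPM in WT library 2 and from 0.708 to 4.04 CPM in KO, and only 3 of 6 KO libraries lay below all WT libraries. Cyp2a5, a cytochrome P450 gene, fell by 2.44 ± 0.50. It ran from 134 CPM in WT library 6 to 1140 CPM in WT library 4 and from 59.4 to 144 CPM in KO, and 4 of 6 KO libraries lay below all WT libraries. Apol9a, Ifit1, Gbp10 and Gbp3, all inducible by interferon, fell by 1.63 ± 0.18, 1.59 ± 0.28, 1.59 ± 0.26 and 1.49 ± 0.29, and each was lower in 6 of 6 KO libraries than in any WT library.

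The other large rises were Pitx3 (log2 fold change 2.95 ± 0.47), Gtpbp4-ps1 (2.76 ± 0.49), Dusp8 (2.13 ± 0.42), Tubb2a (2.09 ± 0.47), Hr (1.82 ± 0.38), Mup6 (1.44 ± 0.29), Tuft1 (1.29 ± 0.24) and Paxx (1.27 ± 0.26). The other large falls were R3hdml (-1.78 ± 0.41), the mitosis kinase gene Wee1 (-1.76 ± 0.38) and Trim80 (-1.53 ± 0.29). All 20 had an edgeR Benjamini-Hochberg adjusted p between 0.00178 for Apol9a and 0.0405 for Tubb2a. Pitx3 lies tail to tail with Elovl3 on chromosome 19, where the annotated ends overlap (46135685 to 46135694), so the reads of both are uncertain. Paxx overlaps Clic3, R3hdml overlaps Hnf4aos, and Acot3 and Acot4 overlap 4732463B04Rik, and their reads are uncertain too. Mup6, Serpina3c, Acot3, Acot4, Cyp2a5, Apol9a, Gbp3, Gbp10 and the pseudogene Gtpbp4-ps1 have close copies with which reads may have been shared.

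**Figure D1:**
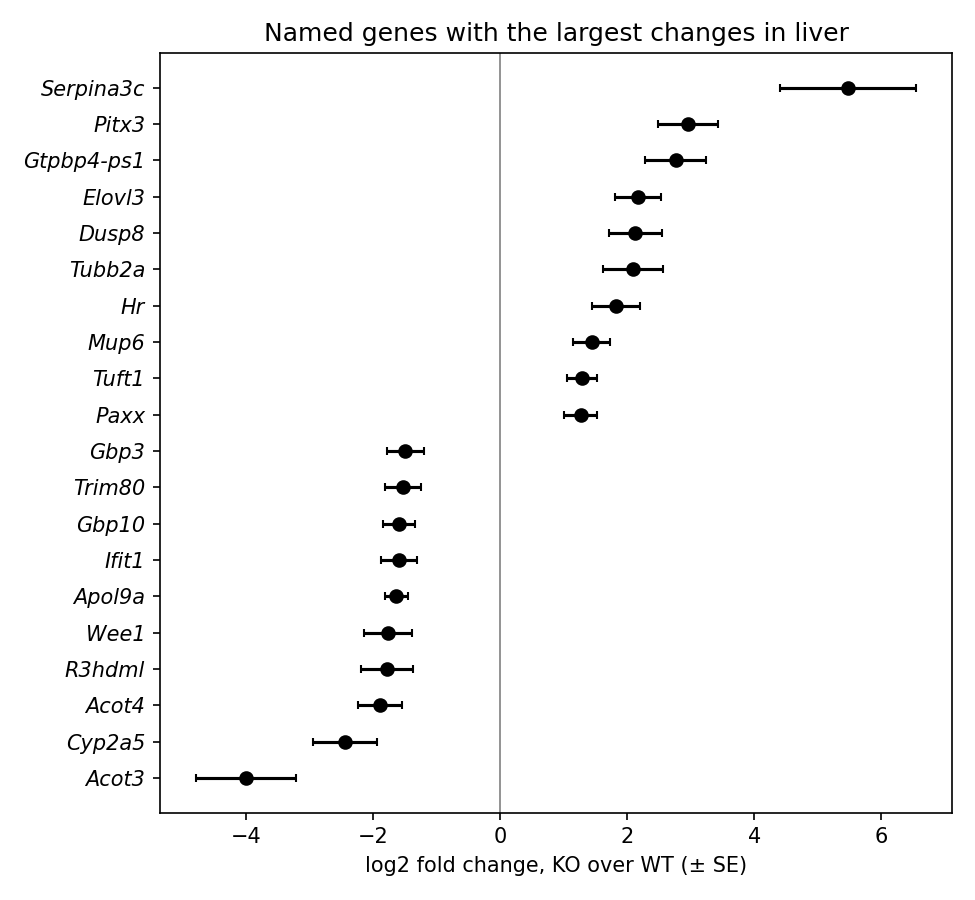
Log2 fold change of KO over WT with its standard error (edgeR, n = 6 per group) for the 10 named genes that rose most and the 10 that fell most. Serpina3c stands at 5.48 and Acot3 at -4.00.

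In all, 396 of 15000 tested genes changed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 172 upward and 224 downward, of which 76 changed at least 2-fold (23 up, 53 down) and 34 had predicted names only. Groups did not overlap for 380 genes, or 2.53%, against 0.216% by chance. The authors' deposited table gave an adjusted p under 0.05 for 834 genes (388 up, 446 down), and 325 of the 396 were among them in the same direction. Its fold changes follow these same counts, so the overlap is no separate evidence. The count fell to 86 without KO library 6, 46 without WT library 2, 25 without WT library 4, 89 without WT library 5 and 235 without KO library 2, and was 700 without WT library 6. It was 1210 with DESeq2, 17 with a macrophage score and 0 with a clock phase score as a covariate (edgeR, 1019 genes at an unadjusted p under 0.05). The macrophage score differed between the groups by -0.962 (exact permutation p = 0.0173, unadjusted) and the clock phase score, made of genes chosen after their values were seen, by 2.49 (exact permutation p = 0.00433, unadjusted).

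Interferon-stimulated genes were lower in KO livers. Of 34 measured, 33 had a negative fold change, 21 fell over all genes tested and 31 fell when adjusted over the list alone, with a median log2 fold change of -0.82. Besides Ifit1, Ddx58, a sensor of viral RNA, fell by 0.46 ± 0.07, Gbp7 by 1.04 ± 0.15, Zbp1 by 1.07 ± 0.16 and Rtp4 by 0.93 ± 0.15 (log2, SE; edgeR, Benjamini-Hochberg adjusted p from 0.00860 to 0.0206). The list score was -0.689 ± 0.424 in KO and 0.689 ± 0.328 in WT (SD, n = 6 each), and the exact permutation p of 0.00216 was the smallest possible (0.0952 after Benjamini-Hochberg adjustment over 44 lists). Camera gave an adjusted p of 4.52e-35, and adjusted p = 0.0779 with an estimated correlation; fry gave an adjusted p of 0.00266. Without WT library 4, 4 interferon genes were called, and 7, 7 and 9 without KO library 6, WT library 2 and WT library 5. With a macrophage score as a covariate 1 was called, and with a clock phase score 0.

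For steatosis, 2 genes of fatty acid synthesis rose. Elovl5, a fatty acid elongase gene, rose from 487 ± 98.8 to 927 ± 260 CPM (log2 0.93 ± 0.20 SE), and Me1, whose enzyme supplies NADPH, rose from 102 ± 17.9 to 181 ± 54.1 CPM (SD, n = 6 each; log2 0.82 ± 0.18 SE; edgeR, Benjamini-Hochberg adjusted p = 0.0293 and 0.0356). Of 20 lipogenesis genes, 2 rose over all genes tested and 2 when adjusted over the list alone, while 19 had positive fold changes with a median of 0.34. The camera adjusted p was 0.000413, and adjusted p = 0.683 with an estimated correlation. Values for Fasn (log2 fold change 0.83 ± 0.47), Scd1 (0.12 ± 0.48) and Srebf1 (0.36 ± 0.38) did not pass the edgeR test. Neither did Cd36 (-0.30 ± 0.51), Cidec (1.81 ± 0.77), Plin2 (-0.04 ± 0.10), Pparg (0.43 ± 0.34) or Fgf21 (0.42 ± 0.46). Genes of triglyceride synthesis and lipid droplets were not called (26 measured, median 0.06, camera adjusted p = 0.546, and 0.000248 with a macrophage score as a covariate), nor were those of fatty acid uptake (median 0.05, mean -0.09, camera adjusted p = 0.944). Neither list had a member passing over all genes tested. When adjusted over the list alone, the lipid droplet gene Cidea (log2 3.85 ± 1.06 SE) and Agpat2 (0.39 ± 0.11 SE) rose and the transporter gene Slc27a1 (-1.45 ± 0.38 SE) fell (edgeR, adjusted p = 0.0456, 0.0456 and 0.0471). Cidea stood at 0.135 and 1.80 CPM in KO libraries 5 and 6, within the WT range of 0.0752 to 2.30 CPM (exact permutation p = 0.0758, unadjusted). Among triglyceride and lipid droplet genes, Dgat2 (-0.38 ± 0.12) and G0s2 (-0.94 ± 0.33) were lower without passing (log2, SE).

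PPAR alpha targets were called lower (median -0.29, 22 of 26 negative, camera adjusted p = 0.00113), with adjusted p = 0.683 with an estimated correlation. The list score was high in WT libraries 1, 2 and 4 (0.864, 1.27 and 0.618), while WT libraries 3 and 6 (-0.616 and -0.781) lay among the KO values (-0.856 to 0.161; exact permutation p = 0.173, unadjusted). Acot3 and Acot4 were the 2 that fell over all genes tested, against 6 that fell and 1 that rose when adjusted over the list alone. Fatty acid oxidation genes had a median of -0.14 (26 measured, 0 called, and 0 when adjusted over the list alone; camera adjusted p = 0.0351), with adjusted p = 0.840 with an estimated correlation; Cpt1a stood at -0.34 ± 0.12 and Acaa1a at -0.37 ± 0.12 (log2, SE). The camera call of the oxidation list was lost without KO library 1 (0.111), 2 (0.0979) or 5 (0.100) and without WT library 1 (0.204), 2 (0.233) or 4 (0.0823). Cholesterol synthesis genes were not called (median 0.16, camera adjusted p = 0.0960), but the list was called higher without KO library 2 (0.0389), 3 (0.0181) or 6 (0.00801) or WT library 3 (0.00637) or 6 (0.00512), over a range up to 0.620 without WT library 1. Pck1 (0.57 ± 0.30) and Cyp7a1, the rate-limiting enzyme of bile acid synthesis (-0.82 ± 0.40), did not pass.

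For inflammation, 3 macrophage markers fell in KO livers. Cd5l, secreted by liver macrophages, fell from 79.2 ± 16.6 to 36.9 ± 12.04 CPM (log2 -1.10 ± 0.19), Adgre1, which encodes F4/80, by 0.87 ± 0.18 and Vsig4 by 0.79 ± 0.18 (log2, SE; edgeR, Benjamini-Hochberg adjusted p = 0.0194, 0.0266 and 0.0368). Of 25 markers, 3 fell over all genes tested, while 14 fell and 1 rose when adjusted over the list alone, with a median of -0.54. The camera adjusted p was 9.47e-10, and adjusted p = 0.632 with an estimated correlation. Cytokine and chemokine genes had a median of -0.29 (26 measured, 0 called, and 0 when adjusted over the list alone; camera adjusted p = 0.00756), with adjusted p = 0.683 with an estimated correlation. Tnf (-0.65 ± 0.67), Il1b (-0.26 ± 0.52), Ccl2 (0.15 ± 0.60) and Cd68 (-0.45 ± 0.21) did not pass. The camera call of the cytokine list was lost without KO library 5 (adjusted p = 0.0703) and without WT library 5 (0.0659).

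For fibrosis, no member of the matrix list was called. Among 38 measured genes, 22 were positive and 16 negative, and 0 passed over all genes or when adjusted over the list alone. The median log2 fold change was 0.07, whereas the mean was -0.02 and camera pointed downward (adjusted p = 0.783). Col1a1 (-0.85 ± 0.46), Col3a1 (0.55 ± 0.43), Acta2 (1.62 ± 0.57), Timp1 (-0.26 ± 0.55) and Tgfb1 (-0.31 ± 0.13) did not pass (log2, SE, edgeR). The list was called, in opposite directions, with a clock phase score (lower, adjusted p = 5.62e-07) or a macrophage score (higher, adjusted p = 1.75e-06) as a covariate in camera.

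**Figure D2:**
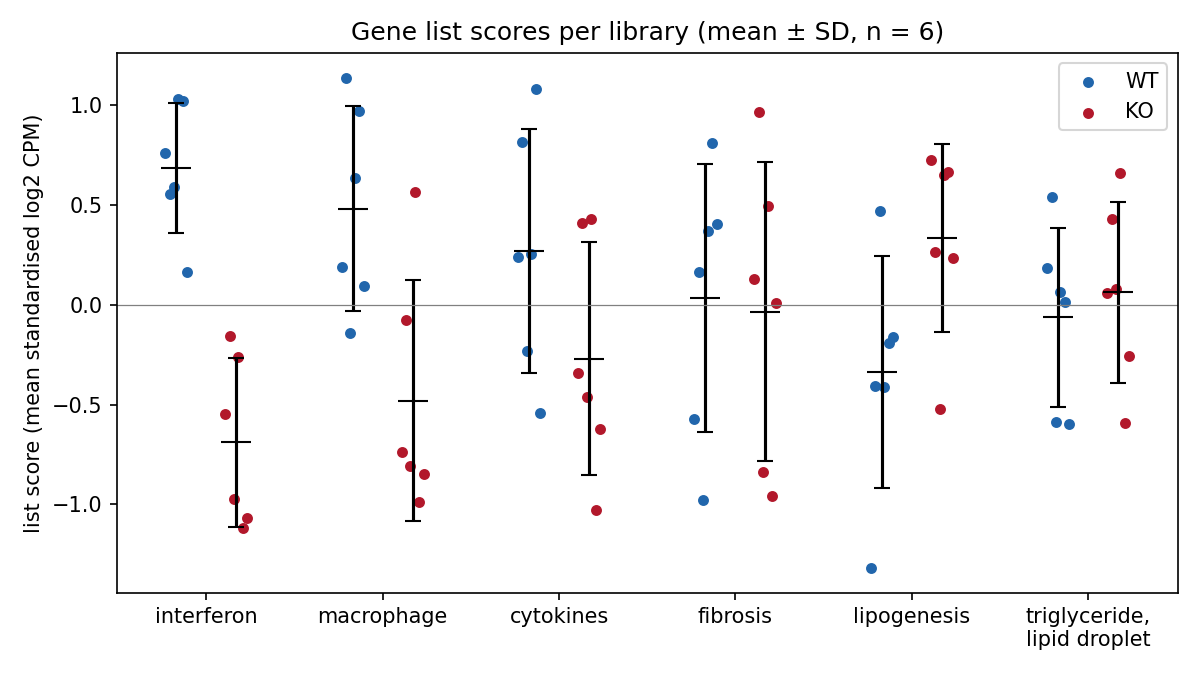
List scores per library (mean of standardised log2 CPM over the members) for 6 gene lists in WT (blue) and KO (red), with mean and SD, n = 6 per group. The groups do not overlap for interferon genes, and they overlap for macrophage, cytokine, fibrosis, lipogenesis and triglyceride genes.

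Camera called 19 of the 44 lists (6 up, 13 down), 0 with an estimated correlation, 1 with fry and 0 by the exact permutation of list scores after adjustment (9 at an unadjusted p under 0.05). Camera also called at least 19 lists in 40 of 100 groupings of the libraries, the real one included, so its calls at the preset correlation did not separate the genotypes from other groupings. Besides lipogenesis, camera called upward the nuclear respiratory chain genes (38 of 38 positive, median 0.11, 1 called over all genes and 1 adjusted over the list alone; adjusted p = 0.000164), with adjusted p = 0.683 with an estimated correlation. The called member was Cycs, which encodes cytochrome c (log2 0.46 ± 0.08). The unfolded protein response list (median 0.29, adjusted p = 0.000201), the mitochondrial DNA genes (0.25, 0.00336), heat shock genes (0.29, 0.00721) and male-biased genes (0.51, 9.65e-06) were also called, each with adjusted p = 0.683 with an estimated correlation. Of these lists, 1 male-biased gene, Elovl3, rose over all genes, and 1 male-biased and 1 unfolded protein response gene when adjusted over the list alone. The male-biased score was lowest in WT libraries 2 (-1.70) and 4 (-1.23), while WT libraries 1, 3 and 6 (0.145, 0.639 and 0.405) lay among the KO values (-0.374 to 0.905; exact permutation p = 0.104, unadjusted). The heat shock call was lost without KO library 5 (0.0514) or WT library 6 (0.0714).

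Downward calls by camera included clock genes (median -0.56, adjusted p = 0.000576), with adjusted p = 0.487 with an estimated correlation. Cry1, a clock repressor gene, rose by 0.96 ± 0.21, while Hlf and Tef, which encode clock output factors, fell by 0.80 ± 0.16 and 0.93 ± 0.20 (log2, SE). Over all genes 1 clock gene rose and 3 fell, against 4 and 11 when adjusted over the list alone. Xenobiotic metabolism genes (median -0.23, adjusted p = 0.00409), female-biased genes (-0.69, 0.00289) and MHC class II genes (-0.35, 0.00336) were called lower, each with adjusted p = 0.683 with an estimated correlation. Nr1i3, the xenobiotic receptor CAR, fell by 1.28 ± 0.24 and Ugt1a1, the bilirubin-conjugating enzyme gene, by 0.56 ± 0.14 (log2, SE). Reads of both are uncertain, since Nr1i3 overlaps Tomm40l (log2 fold change -1.24) and Ugt1a1 overlaps other Ugt1a genes. In the xenobiotic list 3 genes fell over all genes, while 6 fell and 1 rose when adjusted over the list alone. The female-biased score was high in WT libraries 2 (1.20) and 4 (1.17), while the other WT libraries (-0.608 to 0.207) lay in or near the KO range (-0.849 to 0.173; exact permutation p = 0.0887, unadjusted). The counts were 1 and 1 for female-biased genes and 0 and 1 for MHC class II genes. The female-biased gene was Acot3, whose reads are uncertain. It was also counted among the PPAR alpha targets, so the calls of these lists are not independent. The xenobiotic call was lost without KO library 1 (0.0511).

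The cell type scores ask whether other cells made up a different share of the tissue. No score passed the test of a group difference after adjustment over 11 lists. The macrophage score differed by -0.962 (exact permutation p = 0.0173, Benjamini-Hochberg 0.0635), the T and NK cell score by -0.754 (p = 0.0173, 0.0635) and the B and plasma cell score by -0.760 (p = 0.0173, 0.0635; all exact permutation). Skeletal muscle genes (-1.04, 0.137) and neutrophil genes (-0.823, 0.210) were lower without passing. The differences were 0.0512 for stellate cells, -0.484 for sinusoidal endothelium, 0.415 for cholangiocytes, -0.204 for hepatocytes, 0.122 for adipocytes and 0.313 for erythroid cells (adjusted p from 0.429 to 0.892, exact permutation). Camera called the muscle, neutrophil, T and NK, and B cell lists lower (adjusted p = 3.84e-05, 0.00574, 0.00823 and 0.00756), with adjusted p = 0.683, 0.683, 0.619 and 0.683 with an estimated correlation. The B cell call was lost without KO library 5 (0.0598) and with a filter of 1 CPM in 6 libraries (0.189). Under that filter the T and NK list, with 7 of 23 markers measured in the main test, had fewer than 5 members and was not tested. The share of counts from mitochondrial DNA was 5.86% ± 0.354 in KO and 5.37% ± 0.225 in WT (SD, n = 6 each; exact permutation p = 0.0173, Benjamini-Hochberg 0.0519 over 3 library measures). Over all genes 0 muscle, 0 neutrophil, 1 T and NK and 0 B cell genes fell, against 7, 0, 2 and 0 when adjusted over the list alone. The T cell gene was Lck (log2 -1.30 ± 0.30 SE), at a low mean level of 0.318 CPM in KO and 0.785 CPM in WT. Without KO library 4, 2 cell type scores passed.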

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

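Of 310 groups of 6 libraries examined, 16 held a library standing far from the rest, where chance gives 15.5. Each value is the gap to the nearest library divided by the range of the group, and levels are log2 CPM. WT library 6 was low for Ifit1 (0.738; 3.32 against 4.17 to 4.48), Gbp7 (0.668; 4.09 against 4.63 to 4.89) and Per1 (0.724). KO library 5 was high for Fasn (0.652; 10.8 against 8.41 to 9.24) and low for Plin2 (0.682) and Cd22 (0.659). KO library 6 was low for Cyp7a1 (0.711) and high for Acta2 (0.628; 3.76 against 0.46 to 1.69). KO library 2 was high for Fgf21 (0.774), the cell cycle score (0.627) and the TMM factor (0.657). KO library 1 was low for Lck (0.726) and high for Gm6493 (0.729). Slc27a1 was high in KO library 4 (0.693). Bhlhe41 was high in WT library 3 (0.833), and the erythroid score was low in WT library 2 (0.720).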

How the results depend on the processing

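The clock and macrophage covariates were chosen after seeing the data; both scores moved with the groups (unadjusted exact permutation p = 0.00433 and 0.0173), so a lost call need not show a technical source. The 396 genes (172 up, 224 down) became 1210 (567, 643) with DESeq2, 913 (450, 463) with library weights, 257 (94, 163) with total counts only, 182 (56, 126) at 1.5-fold or more because fewer genes qualify, 17 (6, 11) with the macrophage score and 0 (0, 0) with the clock score. With 1 library left out they ranged from 25 to 700 (8 to 320 up, 17 to 380 down), and lowest without WT library 4. The counts were 394 with limma-voom, 392 with RLE and 399 without a filter. Whether the replicate numbers pair the libraries was not settled (correlations from -0.20 to 0.36). KO libraries 2, 4 and 6 correlated best with the WT library of their own number, and KO libraries 1, 3 and 5 with another. The replicate block gave 374 genes (146 up, 228 down), of which 250 were shared with the 396, and a Phb log2 fold change of 0.15. Under the block camera called 18 of the 19 lists, fatty acid oxidation losing its call (adjusted p = 0.0658), and the cholangiocyte list gained one (0.0491). The cause was not tested unless stated.

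Of the 19 lists, camera called 0 with an estimated correlation, fry 1 and the exact permutation 0. With these 3 in that order, adjusted p was 0.0779, 0.00266 and 0.0952 for interferon, 0.632, 0.133 and 0.152 for macrophage, 0.683, 0.202 and 0.238 for lipogenesis, and 0.683, 0.366 and 0.401 for cytokine genes. With the clock score it was 0.151 for cytokine genes and 5.62e-07 for fibrosis. With the macrophage score it was 0.0163 for cytokine genes and 1.75e-06 for fibrosis, both now higher in KO, and 0.000248 for triglyceride and 0.0140 for stellate genes, which gained calls. In all 5 lists gained a call with the clock score, among them gluconeogenesis (0.0422), glucose and insulin (0.0300) and acute phase (1.60e-07), and 13 with the macrophage score, among them gluconeogenesis (0.000248) and adipocyte (0.00489). With 1 library left out camera called 18 to 24 lists and up to 5 gained a call. Calls were also lost with the clock score for PPAR alpha targets (0.337), xenobiotic (0.337), heat shock (0.353) and T and NK genes (0.0553), and with the macrophage score for unfolded protein response (0.128), neutrophil (0.0914), B cell (0.182) and T and NK genes (0.152). With 1 library left out the adjusted p of the cytokine list ranged from 0.000535 to 0.0703 and that of fibrosis from 0.0994 to 0.969, with changes of direction. No cell type score passed with all libraries and up to 2 passed with 1 left out (lowest 0).

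These lists changed direction without passing under that setting, with these adjusted p. With the clock score: unfolded protein response 0.349, fatty acid oxidation 0.337 and stellate 0.788. With the macrophage score: male-biased 0.166, PPAR alpha targets 0.414, female-biased 0.985, MHC class II 0.166, xenobiotic 0.918, fatty acid oxidation 0.846 and cholesterol synthesis 0.865. The stellate list also did so when libraries were left out (range 0.299 to 0.997). The score differences changed sign for stellate (range -0.178 to 0.22), adipocyte (-0.123 to 0.307) and hepatocyte (-0.378 to 0.000593) with 1 library left out.

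No called gene changed direction among those followed. Of their values with 1 library left out, 337 kept and 203 lost the call; under the other alternatives 382 kept and 104 lost it. Genes that had not passed changed sign, in log2: Scd1 with limma-voom (-0.0519), library weights (-0.17), the replicate block (-0.0855) and the clock score (-0.12), Plin2 with library weights (0.0021), Cd36 and Il1b with 1 surrogate variable (0.31 and 0.18). With the clock score these were Phb2 0.0382, Cd36 0.20, Fgf21 -0.69, Cyp7a1 0.24, Il1b 0.90 and Col3a1 -0.38. With the macrophage score they were Fasn -0.0423, Srebf1 -0.10, Cd36 1.06, Plin2 0.0137, Tnf 0.63, Il1b 1.11 and Timp1 0.81. With 1 library left out the ranges were -0.12 to 0.32 for Scd1, -0.0929 to 0.0184 for Plin2, -0.90 to 0.12 for Timp1 and -0.11 to 0.50 for Ccl2. Without a change of sign they were 0.29 to 1.24 for Fasn, 0.17 to 0.72 for Srebf1, -0.50 to -0.00222 for Cd36, 0.08 to 0.71 for Col3a1, 0.06 to 0.64 for Fgf21, -0.88 to -0.02 for Il1b and -1.11 to -0.42 for Tnf.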

Other observations

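The tests of sampling time, of the region beside Adipoq and of the covariates were chosen after the gene results were seen. Tat, which encodes tyrosine aminotransferase, rose by 0.80 ± 0.14, and Prlr, the prolactin receptor gene, fell by 1.08 ± 0.21 (log2, SE, n = 6 per group; edgeR, Benjamini-Hochberg adjusted p = 0.0176 and 0.0267). Foxo1 and Insr, in insulin signalling, fell by 0.48 ± 0.11 and 0.40 ± 0.10, and the complement gene C3 fell by 0.44 ± 0.10. These 5 genes were chosen after their values were seen, from lists that camera did not call with all libraries and no covariate: gluconeogenesis (Tat, Foxo1; adjusted p = 0.478, 7 of 16 positive), growth hormone axis (Prlr; 0.431, 7 of 17), glucose and insulin (Insr; 0.352, 12 of 21) and acute phase (C3; 0.277, 12 of 27). Over all genes 1 gluconeogenesis gene rose and 1 fell, and 1 fell in each of the others; adjusted over the list alone the counts up and down were 3 and 1, 1 and 1, 1 and 1, and 0 and 2. Called genes lay side by side more often than in random draws over all genes: 20 neighbouring pairs within 20 kb changed in the same direction, where 10000 random draws gave a mean of 2.93 and at most 12. Many pairs are paralogs or overlapping genes that can share reads. The draws took no account of gene families or overlaps, so they cannot decide whether there is clustering beyond these.

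The number of changed genes exceeded other groupings of the libraries. In 100 of the splits of the 12 libraries into 6 and 6, 1, the real one, gave 396 genes or more, and the highest other gave 1, so chance assignment can be excluded at that level. For the camera lists it cannot be excluded, since 40 of the 100 splits gave at least the real 19 and the highest other gave 30.

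Interferon-stimulated genes were lower in KO, with a difference in mean log2 CPM of -0.805. With the macrophage score as a covariate it was -0.474 (95% interval -0.795 to -0.153), and 1 interferon gene was called lower. The score is a marker average in bulk tissue and may remove only part of a difference in macrophages. This fit therefore cannot exclude fewer macrophages as the whole source. With the clock phase score the difference was -0.766 (-1.33 to -0.206), and 0 interferon genes were called lower. That score was made of genes chosen after their values were seen and moved with the groups. It therefore cannot decide whether clock phase is a source. An effect of the adipocyte deletion stays open, as does any unrecorded difference in housing or infection, which was not tested.

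Of 24 measured clock genes 1 rose and 3 fell over all genes tested, with 7 positive and 17 negative fold changes, but the list, called by camera at the preset correlation (adjusted p = 0.000576), did not pass by exact permutation (0.152) or in camera (adjusted p = 0.487 with an estimated correlation). These tests look for a shift in 1 direction, while genes of this list moved both ways. Fry without regard to direction, unlike its use elsewhere here, gave an adjusted p of 0.00603. It also passed lists that camera did not call, such as gluconeogenesis (0.00315). A phase score was made from 17 of the 24 genes, 5 of activator phase and 12 output genes, divided after their values were seen. All 17 follow the division, so their medians lying 2.08 apart on the log2 scale and the score (1.25 ± 1.14 in KO, -1.25 ± 1.08 in WT, SD, n = 6 each) describe the choice and are no separate evidence. The groups overlapped in this phase score: KO library 3 (-0.603) lay within the WT range and WT library 6 (0.607) within the KO range. For the score of the 24 genes, a list fixed beforehand, the difference was -0.525 with all libraries and stayed at -0.489 or further from 0 with any 1 left out (unadjusted p at most 0.0173), which argues against 1 library as the cause of that difference. Sampling at different times of day cannot be told apart from a genotype effect on the clock, because no time is used here and it could have followed the groups. With the phase score as a covariate 0 genes passed: the median absolute log2 fold change of the 396 went from 0.546 to 0.395 and the median SE from 0.114 to 0.172, and all 396 kept their direction. The 396 include Cry1, Tef, Hlf and Wee1, which are part of the score, so for these genes the adjustment is circular.

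Kng1 and Kng2, kininogen genes beside Adipoq (chromosome 16, 23146536 to 23158028, GRCm38), rose by 0.70 ± 0.09 and 0.28 ± 0.07 (log2, SE, n = 6 per group; edgeR, Benjamini-Hochberg adjusted p = 0.00534 and 0.0460). Because both are kininogen genes, reads may have been shared between them. They belong to a block of 7 tested genes picked because its values were positive (median 0.543, against -0.172 in 6 flanking genes), of which Gm6493 lies inside Kng2, Gm15746 inside B630019A10Rik, and Rfc4 overlaps Eif4a2, so their reads are uncertain and they are not independent. Its mean z of 2.80 was reached by a window of 7 genes in 1 of 100 splits, the real one (highest other 2.71), but the block was picked in that split, where 5 windows were as extreme (up to -3.38), so a chance run cannot be told apart from a regional effect. A candidate explanation is extra gene copies carried with a Cre transgene built from the Adipoq region. It cannot be told apart from an effect of the deletion, because the Cre driver is not given in the sources used here and any transgene would follow the genotype.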
